A study of Homo sapiens with 9 samples.

How the data were processed

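RNA of the human fibrosarcoma line HT1080 was measured on 9 Affymetrix expression arrays. Per the labels, 3 arrays came from cells without methylthioadenosine phosphorylase (MTAP-negative), 3 from cells with the enzyme (MTAP-positive), and 3 from MTAP-positive cells that had received the MTAP inhibitor MT-DADMe-ImmA at 10 µM for 48 hours before harvest. The series' design text calls the 3 arrays of each group biological replicates. How the MTAP-positive cells were derived is not given in the sources used here.

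The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes; the version and settings of RMA are not given in the sources used here. RMA corrects background, normalises arrays by quantiles and summarises the probes of each probe set, which reduces array-wide differences in brightness. The deposited table listed 54675 probe sets, of which 37201 had no value on any array and 17474 had a value on every array. Every probe set with values lay at or above log2 of 100 on at least 3 arrays, the lowest such value being 6.64, so dim probe sets had already been left out. The remaining values per array still differed slightly in their median, from 8.24 to 8.38, and the balance of higher and lower genes changed when arrays were centred. No detection calls or background levels were used here.

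Probe sets were named through the platform's annotation table. Of the probe sets with values, 15491 carried 1 gene symbol, 841 several and 1142 none, and 8 were control probe sets. After leaving out controls, 15485 probe sets with 1 symbol were kept, 15482 of which matched the current gene table by Entrez number, with 0 symbols changed. Each of the 9453 genes was represented by its probe set with the highest mean over the 9 arrays. A gene was tested if this probe set lay above the 40th percentile of all deposited non-control values (log2 7.96) on at least 3 of 9 arrays, whichever groups they belonged to. This rule was fixed with the design and, because the table had already been filtered, it removed more genes than a filter on a full table would, leaving out 2442 and keeping 7011. MTAP itself was left out of all counts of changed genes, which are over 7010 genes.

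Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the 3 groups as levels was fitted to all 9 arrays, so that the groups shared 1 estimate of the spread, and eBayes was run with its default settings. Changes are log2 differences with the model's standard error (SE), and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. No pseudocount was needed. Precision is limited by the 3 arrays per group, and the median SE of a log2 change was 0.126. Every p-value measures only the spread between these arrays.

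The comparisons, the tests, 32 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered methionine salvage, polyamine metabolism, the methionine and folate cycles, purine synthesis and salvage, protein arginine methyltransferases, matrix proteases, collagens and matrix glycoproteins, integrins and adhesion, the interferon response, inflammatory cytokines with NF-kB targets, cell cycle and replication, p53 targets, cholesterol synthesis, fatty acid synthesis, the amino acid and unfolded protein response, hypoxia and glycolysis, heat shock proteins, TGF-beta and YAP targets, the Wnt pathway, MAPK immediate early and feedback genes, angiogenesis and growth factors, NRF2 targets, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, lysosome and autophagy, cancer-testis antigens, and markers of epithelial, blood, endothelial or smooth muscle, neural or melanocyte, and liver cells. MTAP was left out of its list. The 27 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation between genes of 0.01, and p-values were adjusted over the 27 lists of a comparison. Camera with a correlation estimated from the data, and fry were run as alternatives. Fry tests a list against no change and not against other genes, so ranges of adjusted p over the alternatives leave it out. Member counts are given over all genes tested and, where they differ, adjusted over the list alone.

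Genes named in the text are MTAP, the 8 largest rises and the 8 largest falls per comparison among changed genes whose groups did not overlap on any array, up to 4 changed members per list with the largest change, at most 2 unchanged members per list with the highest mean level, and for genes that moved in several comparisons the 4 in each direction whose smaller change was largest. CDKN2A and CDKN2B, the neighbours of MTAP on the chromosome, were also to be named, but none of their 3 and 2 probe sets had values. Genes outside this rule are marked as chosen after their values were seen.

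The labels number the arrays 1 to 3 within each group. Deviations of same-numbered arrays from their group means correlated over genes at 0.381, 0.247 and 0.152 between MTAP-positive and MTAP-negative cells, and at 0.767, 0.597 and 0.353 between MTAP-positive cells with and without inhibitor, so the numbers were taken as pairing the arrays in these 2 comparisons. No label states what a number stands for. The main tests left the pairing out. A fit with the replicate number as a block was run beside each.

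RNA quality was followed by the difference between the 5' and the 3' control probe sets of ACTB and GAPDH, which becomes more negative as RNA is degraded or copied incompletely. A fit with the ACTB difference as a covariate was added after these values were seen, as was the combination of the replicate block with an estimated correlation. The other alternatives were no filter, a filter at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, centring arrays on their medians, a renewed quantile normalisation, eBayes with trend and robust settings, array weights, a fit of only the 2 groups compared, the replicate block, leaving out each array in turn, a threshold of 0.01, and testing all probe sets.

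Simulated data with the real spread of 7011 genes held 200 changed genes per draw and a cell cycle list shifted by log2 -0.3. The procedure was tested on 20 draws per comparison. For MTAP-positive against MTAP-negative cells it recovered 45.7% of changes of log2 0.5, 95.9% of log2 1 and 99.9% of log2 2, for inhibitor-treated against MTAP-positive cells 47.8%, 96.3% and 99.9%, and for inhibitor-treated against MTAP-negative cells 44.2%, 97.1% and 100%. False calls made up 5.07%, 5.03% and 5.01% of all calls in these comparisons. Because comparisons that share arrays share their chance values, agreement between comparisons is given beside 100 simulations of independent arrays without any effect, and 100 more in which same-numbered arrays correlate as observed.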

Results

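Expression was measured in HT1080 cells, a line grown from a human fibrosarcoma. There were 3 arrays each of MTAP-negative cells, MTAP-positive cells, and MTAP-positive cells treated with 10 µM MT-DADMe-ImmA for 48 hours. MTAP cleaves methylthioadenosine, a by-product of polyamine synthesis, and so starts the salvage of methionine and adenine. MT-DADMe-ImmA is a tight-binding inhibitor of this enzyme. Correlations between arrays over genes, which are not independent replicates, ran from 0.949 to 0.986 within groups and from 0.902 to 0.975 between groups. The first 3 principal components held 52.0%, 18.7% and 13.5% of the variance.

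RNA quality varied between arrays. The 5' minus 3' difference of the ACTB control was -2.50 ± 0.90 in MTAP-negative cells (log2, SD, n = 3), where replicate 3 reached -3.52. It was -1.43 ± 0.45 in MTAP-positive cells and -1.64 ± 0.66 with inhibitor. Exact two-sided permutation tests gave p = 0.2 for MTAP-positive against MTAP-negative cells and p = 0.7 for the inhibitor. Inhibitor-treated against MTAP-negative cells gave an exact permutation p = 0.4, where 0.1 is the smallest p that 3 against 3 arrays allow. These tests leave the pairing by replicate number aside. In all 3 same-numbered pairs ACTB and GAPDH were both more negative in MTAP-negative than in MTAP-positive cells, by 0.48, 1.15 and 1.60 for ACTB in replicates 1 to 3. Exact sign-flip tests of 3 pairs, added after the data were seen, gave p = 0.25 for either control, the smallest p they allow. GAPDH gave -0.61 ± 0.41, -0.18 ± 0.16 and -0.23 ± 0.13 in the same order of groups (SD, n = 3).

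MTAP mRNA followed the labels on every array. Its probe set of highest mean read 11.58 ± 0.19 in MTAP-positive cells, 11.20 ± 0.10 with inhibitor and 4.56 ± 0.41 in MTAP-negative cells (log2, SD, n = 3). The other MTAP probe set with values read 11.63 ± 0.07, 11.39 ± 0.14 and 3.96 ± 0.10, and the rest of the 6 MTAP probe sets had no values. The deposited table kept probe sets that reached 6.64 (log2) on at least 3 arrays, and signal below this level was not shown to be above background. Where a group mean lies below it, folds in the text are counted from 6.64 and given as lower bounds, and log2 changes are differences between array values. MTAP was thus higher by at least 4.94 (log2) in MTAP-positive and by at least 4.56 in inhibitor-treated cells. The array values differed by 7.02 ± 0.18 between MTAP-positive and MTAP-negative cells (log2 ± SE; limma, Benjamini-Hochberg adjusted p = 1.21e-08) and by 6.65 ± 0.18 between inhibitor-treated and MTAP-negative cells. Between MTAP-positive cells with and without inhibitor it differed by -0.38 ± 0.18, which did not pass the test (adjusted p = 0.197).

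**Figure D1:**
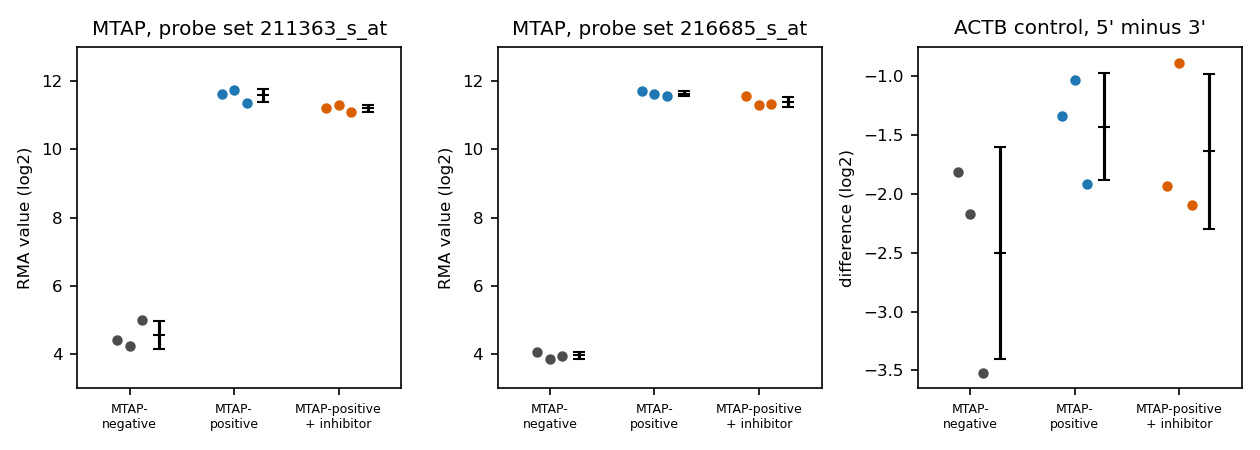
RMA values (log2) of the MTAP probe sets with values and the ACTB 5' minus 3' control difference (log2) on each of the 9 arrays, by group; points are arrays, and bars the group mean and SD. MTAP has a mean of 4.56 or lower in MTAP-negative cells and of 11.20 or higher in the other groups, while the control difference overlaps between groups and is lower in the MTAP-negative array of all 3 same-numbered pairs with MTAP-positive arrays.

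The first comparison asked which genes differed between cells with and without MTAP. PTGES, the inducible prostaglandin E synthase, was at least 5.65-fold higher in MTAP-positive cells, at 9.14 ± 0.29 against 6.18 ± 0.15 (log2, SD, n = 3), and the matrix glycoproteins THBS2 and FN1 were 3.79-fold and 2.53-fold higher. The interferon-response gene IFITM1 (at least 1.86-fold) and the hypoxia-response genes ALDOC (4.30-fold) and VEGFA (2.33-fold) were also higher. The stromelysin MMP3 and the secreted Wnt inhibitor DKK1 were 3.42-fold and 3.74-fold lower.

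Of 7010 genes, 1336 differed between MTAP-positive and MTAP-negative cells (limma, Benjamini-Hochberg adjusted p below 0.05), 820 higher and 516 lower. Of these, 142 changed by at least 2-fold, 117 higher and 25 lower. The groups did not overlap on any array for 35.2% of genes, where chance gives 10%. In every gene named in the text as changed, the 3 arrays of each group lay apart from those of the other. Large rises included LTBP3, a binding protein of latent TGF-beta (2.56 ± 0.52, log2 ± SE), GXYLT2 (2.24 ± 0.41) and the integrin subunit ITGA10 (2.19 ± 0.19). Other genes with large differences between array values had MTAP-negative means below 6.64, so that only lower bounds counted from that level hold. They were PTGES (2.96 ± 0.16, adjusted p = 6.40e-06, at least 5.65-fold) and the annexin ANXA10 (2.56 ± 0.15, at least 2.55). SCG2, which encodes a granin of secretory vesicles (2.57 ± 0.19), the nuclear receptor NR4A2 (2.57 ± 0.28) and PAEP, which encodes glycodelin (2.32 ± 0.21), rose by at least 0.71, 1.05 and 0.63. LTBP3 varied widely among MTAP-negative arrays (7.95 ± 1.39, SD). LTBP3 did not pass with the ACTB covariate (adjusted p = 0.0804), with adjusted p from 4.89e-04 to 0.0804 over its alternatives. The largest falls were DKK1 (-1.90 ± 0.22, adjusted p = 4.24e-04), MMP3 (-1.77 ± 0.15), the metalloprotease ADAMTS6 (-1.74 ± 0.16) and the growth factor NRG1 (-1.61 ± 0.11). The BCL2 relative BCL2A1 (-1.56 ± 0.16), tissue factor F3 (-1.35 ± 0.13), the phospholipase PLCB4 (-1.34 ± 0.24) and DKK3 (-1.34 ± 0.22) followed.

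Camera with the preset correlation called 12 of 27 gene lists with MTAP, 7 with the inhibitor and 17 between inhibitor-treated and MTAP-negative cells. With an estimated correlation 0 passed, and the lowest adjusted p was 0.113, 0.226 and 0.0945. Of 25 tested collagens and matrix glycoproteins 15 were higher and 0 lower, or 17 and 1 adjusted over the list alone. Besides THBS2 (1.92 ± 0.16) and FN1 (1.34 ± 0.15) they included the laminin chain LAMA5 (0.96 ± 0.11). For collagens, the median log2 change was 0.51, with camera adjusted p = 3.67e-05, and adjusted p = 0.308 with an estimated correlation (5.67e-07 to 0.347 over the alternatives of camera). Matrix proteases and their inhibitors had 10 of 18 members higher and 1, MMP3, lower, or 11 and 1 adjusted over the list alone. The protease inhibitor SERPINE2 rose by 1.20 ± 0.10 and the gelatinase MMP2 by 1.04 ± 0.19, while the abundant collagenase MMP1 differed by 0.07 ± 0.09 (adjusted p = 0.604). For matrix proteases, the median log2 change was 0.44, with camera adjusted p = 0.00242, and adjusted p = 0.129 with an estimated correlation (5.57e-04 to 0.188 over the alternatives of camera). Integrins and adhesion molecules had 9 of 21 members higher and 1 lower, the same as adjusted over the list alone. ITGB5 rose by 0.92 ± 0.18, and the member that fell was ALCAM (-0.96 ± 0.19). ALCAM did not pass with the mean of its probe sets (adjusted p = 0.0882) or with the ACTB covariate (0.0685), with adjusted p from 3.17e-04 to 0.0882 over its alternatives. For integrins, the median log2 change was 0.21, with camera adjusted p = 0.00447, and adjusted p = 0.179 with an estimated correlation (3.27e-04 to 0.310 over the alternatives of camera). The call for integrins was also lost without probe sets that can bind several transcripts (adjusted p = 0.218). Among angiogenesis and growth factor genes 6 of 14 were higher and 1, NRG1, was lower, or 7 and 2 adjusted over the list alone. The receptor NRP1 rose by 1.35 ± 0.09 and VEGFC by 0.98 ± 0.10. For angiogenesis genes, the median log2 change was 0.40, with camera adjusted p = 0.00749, and adjusted p = 0.164 with an estimated correlation (4.98e-04 to 0.188 over the alternatives of camera).

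The interferon response list had 9 of 16 tested members higher and 0 lower, or 10 and 0 adjusted over the list alone. IFITM1 rose by at least 0.89 counted from 6.64, the transcription factor IRF9 by 1.33 ± 0.17, the immunoproteasome subunit PSMB9 by 1.26 ± 0.19 and IFI35 by 1.25 ± 0.13, whereas IFITM3 differed by 0.04 ± 0.11 (adjusted p = 0.840). For interferon genes, the median log2 change was 0.78, with camera adjusted p = 1.29e-04, and adjusted p = 0.179 with an estimated correlation (1.96e-07 to 0.298 over the alternatives of camera). The call for interferon genes was also lost with the filter at the 60th percentile (adjusted p = 0.0803). There its median log2 change was 0.31. Inflammatory cytokines and NF-kB targets had 7 of 13 members higher and 0 lower, or 8 and 0 adjusted over the list alone. They included PTGES, the cytokine LIF (0.92 ± 0.09) and the hormone STC1 (1.07 ± 0.11), while CXCL8 differed by 0.16 ± 0.14 and did not pass (adjusted p = 0.483). For inflammatory genes, the median log2 change was 0.57, with camera adjusted p = 2.11e-04, and adjusted p = 0.113 with an estimated correlation (6.14e-05 to 0.168 over the alternatives of camera). Hypoxia and glycolysis genes had 17 of 33 members higher and 2 lower, or 18 and 2 adjusted over the list alone. ALDOC rose by 2.10 ± 0.11 and VEGFA by 1.22 ± 0.14, while the abundant lactate dehydrogenase LDHA differed by 0.11 ± 0.09 (adjusted p = 0.405). For hypoxia genes, the median log2 change was 0.31, with camera adjusted p = 2.37e-04, and adjusted p = 0.179 with an estimated correlation (8.37e-05 to 0.191 over the alternatives of camera).

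Lysosome and autophagy genes had 7 of 23 members higher and 0 lower, the same as adjusted over the list alone, among them the glucosidase GAA (1.35 ± 0.25) and the cholesterol transporter NPC1 (0.97 ± 0.11). For lysosome genes, the median log2 change was 0.21, with camera adjusted p = 0.0287, and adjusted p = 0.562 with an estimated correlation (0.00541 to 0.607 over the alternatives of camera). The call for lysosome genes was also lost with the filter at the 60th percentile (adjusted p = 0.0659), without MTAP-negative replicate 3 (0.0530), or without MTAP-positive replicate 1 (0.0646) or 3 (0.0728). The amino acid and unfolded protein response list had 7 of 36 members higher and 0 lower, or 9 and 0 adjusted over the list alone, led by the mTOR inhibitor DDIT4 (1.39 ± 0.13). For amino acid response genes, the median log2 change was 0.17, with camera adjusted p = 0.0383, and adjusted p = 0.525 with an estimated correlation (0.0148 to 0.525 over the alternatives of camera). The call for amino acid response genes was also lost with array weights (adjusted p = 0.165), without MTAP-negative replicate 2 (0.0849), or without MTAP-positive replicate 1 (0.0984) or 2 (0.0536).

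Of cell cycle and replication genes 9 of 48 were lower and 0 higher, the same as adjusted over the list alone. The cyclin CCNE1 changed by -0.85 ± 0.13 and the phosphatase CDC25A by -0.78 ± 0.12. CDC25A did not pass with the mean of its probe sets (adjusted p = 0.0903), with adjusted p from 2.38e-04 to 0.0903 over its alternatives. For cell cycle genes, the median log2 change was -0.19, with camera adjusted p = 0.00352, and adjusted p = 0.475 with an estimated correlation (3.03e-05 to 0.475 over the alternatives of camera). The call for cell cycle genes was also lost without MTAP-positive replicate 3 (adjusted p = 0.0728). Fry, which tests against no change and not against other genes, gave adjusted p = 0.0672. Of ribosome biogenesis genes 4 of 22 were lower and 0 higher, or 5 and 0 adjusted over the list alone, led by the nucleolar protein NOP58 (-0.60 ± 0.12). For ribosome biogenesis, the median log2 change was -0.20, with camera adjusted p = 6.00e-04, and adjusted p = 0.179 with an estimated correlation (1.19e-04 to 0.179 over the alternatives of camera).

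Methionine salvage, the pathway that MTAP starts, had 1 of 5 other members lower, APIP (-0.42 ± 0.12), or 3 adjusted over the list alone. APIP did not pass in 9 alternatives, among them without MTAP-negative replicate 1 (adjusted p = 0.0721), 2 (0.105) or 3 (0.0509), without MTAP-positive replicate 1 (0.0901) or 3 (0.119), or without inhibitor-treated replicate 1 (0.0502), 2 (0.0513) or 3 (0.0577), with adjusted p from 0.00335 to 0.119 over its alternatives. For methionine salvage, the median log2 change was -0.24, with camera adjusted p = 0.0432, and adjusted p = 0.330 with an estimated correlation (0.0214 to 0.348 over the alternatives of camera). The call for methionine salvage was also lost in 10 other alternatives, among them without MTAP-negative replicate 2 (adjusted p = 0.0564) or 3 (0.0825), or without MTAP-positive replicate 2 (0.0575) or 3 (0.0995). Polyamine genes had 2 of 16 members higher and 1 lower, the same as adjusted over the list alone. The lower one was ODC1, which makes putrescine (-0.43 ± 0.12), and the higher ones were arginase ARG2 (0.60 ± 0.14) and spermine oxidase SMOX (0.49 ± 0.14). ODC1 did not pass with only the 2 groups fitted (adjusted p = 0.0766), with the ACTB covariate (0.131), without MTAP-negative replicate 1 (0.0848) or 3 (0.0935), or without MTAP-positive replicate 3 (0.1), with adjusted p from 0.00204 to 0.131 over its alternatives. ARG2 did not pass without MTAP-negative replicate 3 (adjusted p = 0.0553) or without MTAP-positive replicate 3 (0.0501), with adjusted p from 7.08e-04 to 0.0553 over its alternatives. SMOX did not pass in 10 alternatives, among them without MTAP-negative replicate 1 (adjusted p = 0.0678), 2 (0.0738) or 3 (0.119), without MTAP-positive replicate 1 (0.111) or 3 (0.0922), or without inhibitor-treated replicate 3 (0.0610), with adjusted p from 0.0119 to 0.140 over its alternatives. For polyamine metabolism, the median log2 change was -0.09, with camera adjusted p = 0.671, and adjusted p = 0.716 with an estimated correlation (0.163 to 0.975 over the alternatives of camera). Of arginine methyltransferase genes and cofactors 3 of 11 were lower, the same as adjusted over the list alone: WDR77 (-0.52 ± 0.12), RIOK1 (-0.69 ± 0.14) and PRMT3 (-0.55 ± 0.13). WDR77 did not pass without MTAP-positive replicate 3 (adjusted p = 0.0511), with adjusted p from 0.00241 to 0.0511 over its alternatives. PRMT3 did not pass with the ACTB covariate (adjusted p = 0.0811), without MTAP-negative replicate 2 (0.0524) or without MTAP-positive replicate 3 (0.0591), with adjusted p from 0.00292 to 0.0811 over its alternatives. For arginine methyltransferases, the median log2 change was -0.13, with camera adjusted p = 0.112, and adjusted p = 0.420 with an estimated correlation (0.0442 to 0.675 over the alternatives of camera).

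Centring arrays on their medians turned the share of higher genes from 61.4% to 43.2% of the genes changed, and a renewed quantile normalisation to 48.0%. Changes of at least 2-fold stayed mostly rises after centring (100 higher, 33 lower). Uncentred arrays gave 353 higher of 502 genes with adjusted p below 0.01. The 1336 genes became 745 and 876 without MTAP-negative replicates 3 and 2, and 782 without MTAP-positive replicate 3. They became 1917 with the replicate block, 752 with only the 2 groups fitted and 470 with the ACTB covariate. With this covariate the median SE of the called genes rose from 0.122 to 0.156, their median absolute log2 change went from 0.56 to 0.54, all 1336 kept their sign and 458 still passed.

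**Figure D2:**
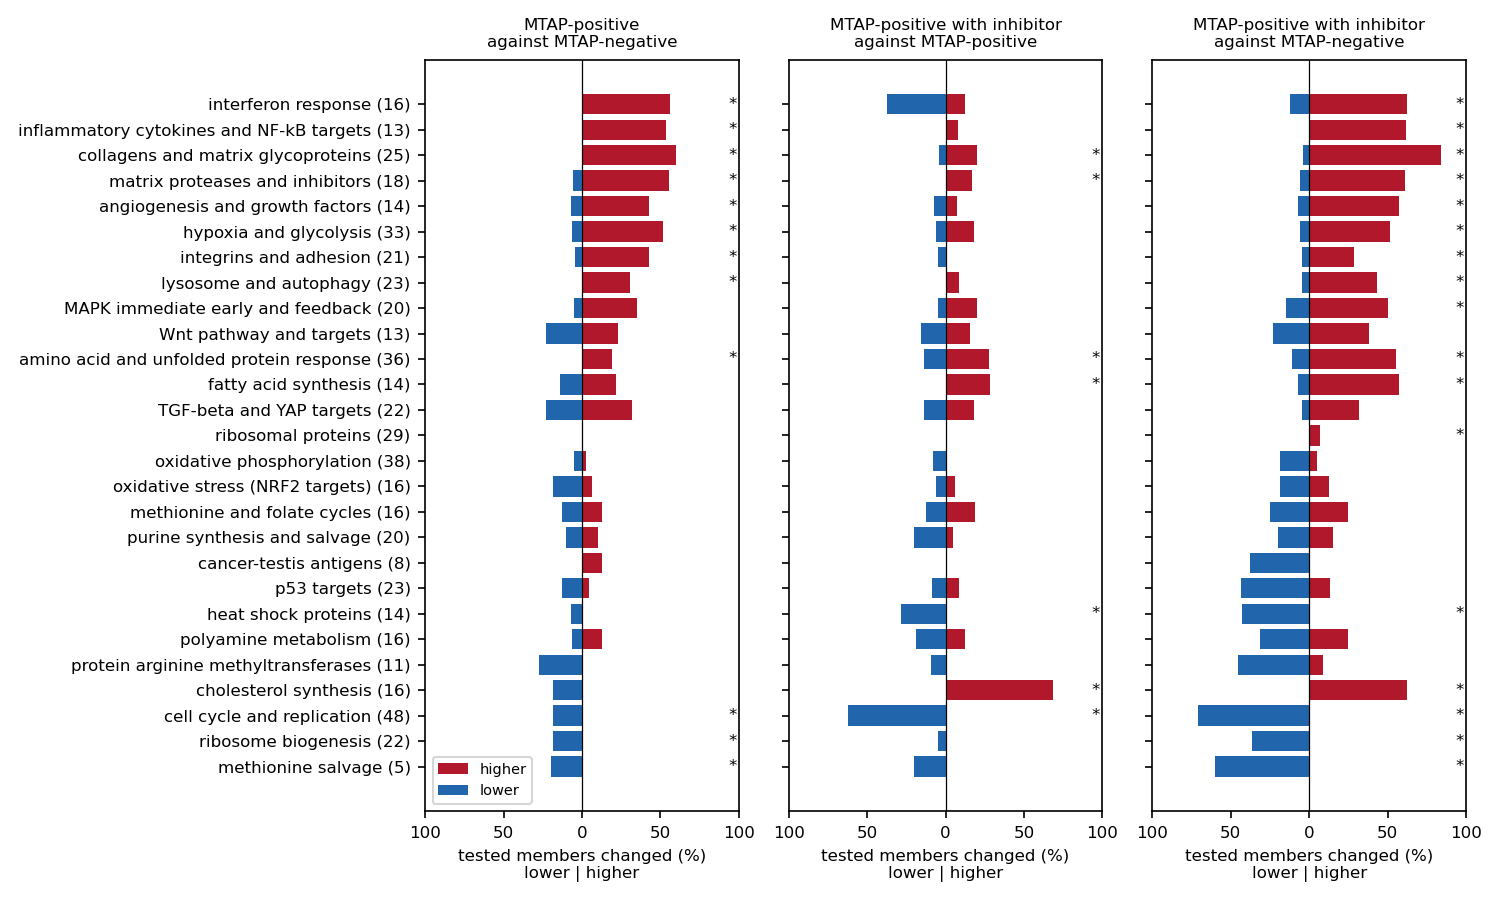
Percent of the tested members of each gene list that were higher (right, red) or lower (left, blue) in each of the 3 comparisons, with the number of tested members in brackets; a star marks camera adjusted p below 0.05 with the preset correlation. Cell cycle genes lie on the lower side and matrix genes mainly on the higher side in all 3 panels, and 0 lists passed in any panel with an estimated correlation.

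The next comparison asked what 48 hours of inhibitor did to MTAP-positive cells. CCNE2, a cyclin of entry into S phase, was at least 2.33-fold lower in inhibitor-treated cells (6.48 ± 0.29 against 7.86 ± 0.39, log2, SD, n = 3), and the condensin subunit NCAPG and the histone H2AX were 2.39-fold and 2.41-fold lower. The cholesterol synthesis genes MSMO1 and HMGCS1 were 2.42-fold and 2.41-fold higher, as was asparagine synthetase ASNS of the response to amino acid shortage (2.54-fold). The gelatinase MMP9 was 3.36-fold higher.

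The inhibitor changed 1042 of 7010 genes, 446 higher and 596 lower, of which 60 changed by at least 2-fold, 34 higher and 26 lower. With the replicate number as a block 1589 genes changed. For 36.4% of genes the groups did not overlap on any array, against 10% by chance. The largest rises were PAEP (2.20 ± 0.21, log2 ± SE; limma, Benjamini-Hochberg adjusted p = 7.18e-04), TEX19 (1.93 ± 0.29), the noncoding RNA PAX8-AS1 (1.83 ± 0.24) and MMP9 (1.75 ± 0.25). The cytokine receptor OSMR (1.75 ± 0.13), TXNIP, an inhibitor of thioredoxin (1.64 ± 0.21), the peptide hormone APLN (1.61 ± 0.15) and SUSD1 (1.60 ± 0.17) followed. For OSMR, 2 of 3 probe sets had the opposite sign, down to -0.82. OSMR did not pass with the mean of its probe sets (adjusted p = 0.730), with adjusted p from 5.41e-05 to 0.730 over its alternatives. The largest falls by array values were CCNE2 (-1.39 ± 0.21, adjusted p = 0.00319; at least 1.22 counted from 6.64), the Wnt receptor FZD1 (-1.35 ± 0.15), GDAP1 (-1.29 ± 0.17) and H2AX (-1.27 ± 0.16). NCAPG (-1.26 ± 0.14), CDCA3 (-1.23 ± 0.14), the chaperone DNAJB6 (-1.20 ± 0.11) and the nuclear lamin LMNB1 (-1.19 ± 0.27) followed. LMNB1 did not pass without MTAP-positive replicate 1 (adjusted p = 0.0540), or without inhibitor-treated replicate 2 (0.0625) or 3 (0.0811), with adjusted p from 0.00235 to 0.0811 over its alternatives. The 1042 genes became 372 without inhibitor-treated replicate 3, 603 without inhibitor-treated replicate 2, 627 without inhibitor-treated replicate 1 and 667 without MTAP-positive replicate 1.

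Cell cycle and replication genes had 30 of 48 lower and 0 higher, or 33 and 0 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, changed by -1.02 ± 0.17 and the replication protein MCM10 by -0.96 ± 0.17, while the G1 cyclin CCND1 differed by 0.04 ± 0.17 (adjusted p = 0.887). For cell cycle genes, the median log2 change was -0.55, with camera adjusted p = 5.80e-14, and adjusted p = 0.226 with an estimated correlation (1.52e-15 to 0.226 over the alternatives of camera). Heat shock proteins had 4 of 14 members lower and 0 higher, the same as adjusted over the list alone. They included the chaperone DNAJA1 (-0.63 ± 0.09), while the abundant HSP90AA1 differed by -0.17 ± 0.10 (adjusted p = 0.281). For heat shock proteins, the median log2 change was -0.17, with camera adjusted p = 0.0114, and adjusted p = 0.436 with an estimated correlation (0.00494 to 0.633 over the alternatives of camera). The call for heat shock proteins was also lost without probe sets that can bind several transcripts (adjusted p = 0.0957), with array weights (0.0539) or without MTAP-positive replicate 2 (0.0617).

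Cholesterol synthesis had 11 of 16 tested members higher and 0 lower, or 15 and 0 adjusted over the list alone. MSMO1 rose by 1.27 ± 0.16, HMGCS1 by 1.27 ± 0.18 and DHCR7 by 1.02 ± 0.18, while lanosterol synthase LSS differed by 0.27 ± 0.11 (adjusted p = 0.129). For cholesterol synthesis, the median log2 change was 0.75, with camera adjusted p = 5.21e-11, and adjusted p = 0.226 with an estimated correlation (1.11e-11 to 0.255 over the alternatives of camera). Fatty acid synthesis genes had 4 of 14 members higher and 0 lower, or 5 and 0 adjusted over the list alone. They were led by the desaturase SCD (0.71 ± 0.13), while fatty acid synthase FASN differed by 0.74 ± 0.41 (adjusted p = 0.259). FASN passed with only the 2 groups fitted (adjusted p = 0.0135), with adjusted p from 0.0135 to 0.435 over its alternatives. For fatty acid synthesis, the median log2 change was 0.27, with camera adjusted p = 0.00189, and adjusted p = 0.226 with an estimated correlation (5.22e-04 to 0.462 over the alternatives of camera). The call for fatty acid synthesis was also lost without probe sets that can bind several transcripts (adjusted p = 0.0836). There its median log2 change was 0.11.

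The amino acid and unfolded protein response list split. Of 36 members 10 were higher and 5 lower, or 17 and 5 adjusted over the list alone. The higher members included ASNS (1.35 ± 0.12), DDIT4 (0.94 ± 0.13) and the transcription factor DDIT3 (0.85 ± 0.14). ATF4 differed by 0.52 ± 0.16 (adjusted p = 0.0501) and passed in 8 alternatives, with adjusted p from 0.00951 to 0.149. The 5 lower members, known from folding in the endoplasmic reticulum and named after their values were seen, were CRELD2 (-0.77 ± 0.14), MANF (-0.65 ± 0.13), SDF2L1 (-0.60 ± 0.11), the chaperone HSPA5 (-0.40 ± 0.11) and DNAJC3 (-0.31 ± 0.09). MANF did not pass without inhibitor-treated replicate 3 (adjusted p = 0.0566), with adjusted p from 0.00273 to 0.0566 over its alternatives. HSPA5 did not pass with the ACTB covariate (adjusted p = 0.0569), without MTAP-positive replicate 1 (0.107) or 2 (0.0619), or without inhibitor-treated replicate 1 (0.0665), 2 (0.116) or 3 (0.126), with adjusted p from 0.0165 to 0.126 over its alternatives. DNAJC3 did not pass in 13 alternatives, among them without MTAP-negative replicate 1 (adjusted p = 0.0589) or 3 (0.0536), without MTAP-positive replicate 1 (0.0643), 2 (0.0672) or 3 (0.0926), or without inhibitor-treated replicate 1 (0.104), 2 (0.128) or 3 (0.101), with adjusted p from 0.00753 to 0.153 over its alternatives. For amino acid response genes, the median log2 change was 0.29, with camera adjusted p = 1.37e-04, and adjusted p = 0.361 with an estimated correlation (4.46e-06 to 0.361 over the alternatives of camera).

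Some matrix genes were also higher with the inhibitor. Of collagens and matrix glycoproteins 5 of 25 were higher and 1 lower, or 9 and 2 adjusted over the list alone, led by the crosslinking enzyme LOX (0.74 ± 0.12). For collagens, the median log2 change was 0.26, with camera adjusted p = 0.00199, and adjusted p = 0.600 with an estimated correlation (5.76e-04 to 0.660 over the alternatives of camera). Fry, which tests against no change and not against other genes, gave adjusted p = 0.0754. Of matrix proteases 3 of 18 were higher and 0 lower, the same as adjusted over the list alone: MMP9 and the plasminogen activators PLAU (0.40 ± 0.11) and PLAT (0.43 ± 0.11). PLAU did not pass without MTAP-positive replicate 1 (adjusted p = 0.0647) or 2 (0.0685), or without inhibitor-treated replicate 1 (0.0891), 2 (0.0855) or 3 (0.0946), with adjusted p from 0.0119 to 0.0946 over its alternatives. PLAT did not pass without MTAP-positive replicate 1 (adjusted p = 0.0729) or 3 (0.0878), or without inhibitor-treated replicate 1 (0.0724), 2 (0.0765) or 3 (0.134), with adjusted p from 0.00226 to 0.134 over its alternatives. For matrix proteases, the median log2 change was 0.18, with camera adjusted p = 0.0275, and adjusted p = 0.226 with an estimated correlation (0.0215 to 0.703 over the alternatives of camera). The call for matrix proteases was also lost with the filter at the 60th percentile (adjusted p = 0.125), with the mean of its probe sets (0.0603) or without probe sets that can bind several transcripts (0.703). Interferon response genes went both ways, with 2 of 16 higher and 6 lower, the same as adjusted over the list alone. IFI35 (-0.69 ± 0.13), IFIT3 (-0.71 ± 0.15) and ISG15 (-0.67 ± 0.16) were among those that fell. IFIT3 did not pass without inhibitor-treated replicate 3 (adjusted p = 0.0547), with adjusted p from 0.00120 to 0.0547 over its alternatives. ISG15 did not pass without MTAP-positive replicate 1 (adjusted p = 0.0575) or without inhibitor-treated replicate 3 (0.0955), with adjusted p from 0.00139 to 0.0955 over its alternatives. For interferon genes, the median log2 change was -0.08, with camera adjusted p = 0.506, and adjusted p = 0.757 with an estimated correlation (0.0151 to 0.993 over the alternatives of camera).

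Around the enzyme itself, 1 of 5 methionine salvage genes fell, ADI1 (-0.51 ± 0.11), or 2 adjusted over the list alone. ADI1 did not pass without inhibitor-treated replicate 2 (adjusted p = 0.0509) or 3 (0.0745), with adjusted p from 0.00156 to 0.0745 over its alternatives. For methionine salvage, the median log2 change was 0.05, with camera adjusted p = 0.579, and adjusted p = 0.757 with an estimated correlation (0.454 to 0.891 over the alternatives of camera). The median of this list had the opposite sign to its mean and test. Polyamine genes had 2 of 16 members higher and 3 lower, or 2 and 4 adjusted over the list alone. Spermidine synthase SRM (-0.52 ± 0.13), the antizyme inhibitor AZIN1 (-0.75 ± 0.10) and the antizyme OAZ2 (-0.59 ± 0.15) were lower, and ODC1 differed by -0.33 ± 0.12 (adjusted p = 0.0824). ODC1 passed with trend and robust settings (adjusted p = 0.0458) and without MTAP-negative replicate 2 (adjusted p = 0.0468). SRM did not pass without MTAP-positive replicate 1 (adjusted p = 0.0731) or 2 (0.0523), or without inhibitor-treated replicate 1 (0.0626), 2 (0.0517) or 3 (0.104), with adjusted p from 0.00733 to 0.104 over its alternatives. OAZ2 did not pass without MTAP-positive replicate 1 (adjusted p = 0.0839), or without inhibitor-treated replicate 1 (0.0587) or 3 (0.124), with adjusted p from 0.00468 to 0.124 over its alternatives. For polyamine metabolism, the median log2 change was 0.00, with camera adjusted p = 0.889, and adjusted p = 0.947 with an estimated correlation (0.199 to 0.993 over the alternatives of camera). Methionine and folate cycle genes had 3 of 16 members higher and 2 lower, the same as adjusted over the list alone, with cystathionine synthase CBS at 0.87 ± 0.10 and the mitochondrial enzyme SHMT2 at 0.55 ± 0.09. For the methionine and folate cycles, the median log2 change was 0.07, with camera adjusted p = 0.577, and adjusted p = 0.757 with an estimated correlation (0.224 to 0.757 over the alternatives of camera). Purine genes had 1 of 20 members higher and 4 lower, or 2 and 4 adjusted over the list alone. For purine genes, the median log2 change was -0.06, with camera adjusted p = 0.889, and adjusted p = 0.955 with an estimated correlation (0.703 to 0.993 over the alternatives of camera). The arginine methyltransferase gene that changed was PRMT6 (-0.94 ± 0.13). For arginine methyltransferases, the median log2 change was -0.09, with camera adjusted p = 0.704, and adjusted p = 0.826 with an estimated correlation (0.0957 to 0.993 over the alternatives of camera).

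**Figure D3:**
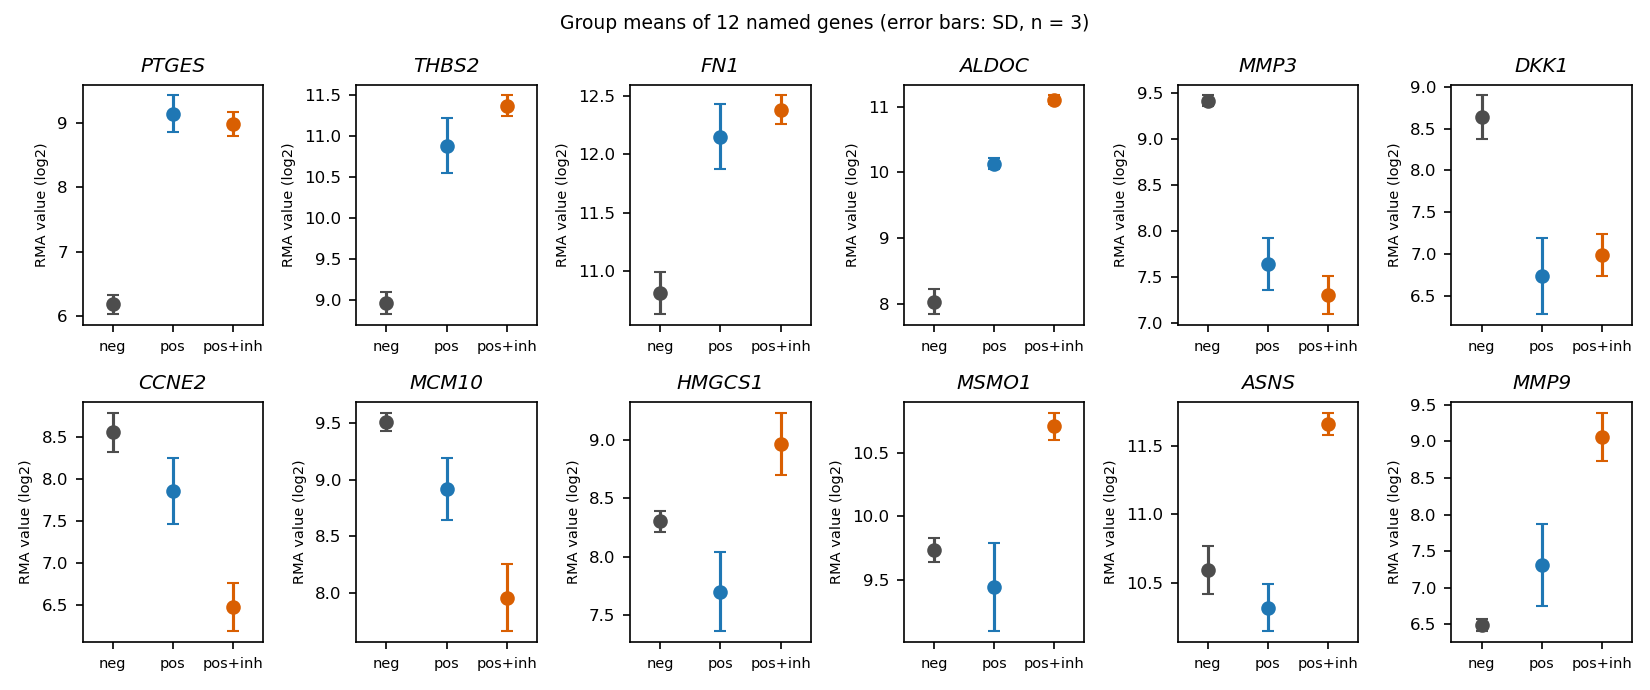
RMA values (log2) of 12 named genes in MTAP-negative cells (neg), MTAP-positive cells (pos) and MTAP-positive cells with inhibitor (pos+inh); points are group means, bars the SD of 3 arrays, and each panel has its own axis, which does not start at 0. PTGES, THBS2 and FN1 are higher in both MTAP-positive groups, MMP3 and DKK1 are lower, and HMGCS1, MSMO1, ASNS and MMP9 are highest with inhibitor.

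Inhibitor-treated MTAP-positive cells were also compared with MTAP-negative cells, on arrays shared with the comparisons above. PAEP was at least 7.12-fold higher in inhibitor-treated cells (9.48 ± 0.02 against 4.96 ± 0.12, log2, SD, n = 3), TXNIP 13.4-fold and ALDOC 8.45-fold, while MMP3 was 4.31-fold and CCNE2 at least 3.77-fold lower. The matrix glycoproteins THBS2 and FN1 and the desaturase SCD were 5.31-fold, 2.96-fold and 2.67-fold higher.

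Here 2613 of 7010 genes differed, 1351 higher and 1262 lower, of which 357 changed by at least 2-fold, 245 higher and 112 lower (limma, Benjamini-Hochberg adjusted p below 0.05). Centring arrays on their medians gave 1142 higher and 1565 lower genes, and a renewed quantile normalisation 1192 and 1449. The groups did not overlap for 54.6% of genes, against 10% by chance. Large rises also included the hyaluronan-degrading protein CEMIP (3.02 ± 0.36, log2 ± SE). PAX8-AS1, PTGES, NR4A2 and SCG2, with MTAP-negative means below 6.64, rose by at least 2.74, 2.34, 1.68 and 1.47 counted from that level. Large falls included DKK1 (-1.66 ± 0.22), MYBL1 (-1.60 ± 0.17), CEP78 (-1.58 ± 0.14), TCF19 (-1.57 ± 0.15) and MCM10 (-1.55 ± 0.17). Without the probe sets that can bind several transcripts 4548 genes were tested and 1732 differed, and with every probe set tested 3961 did.

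Collagens and matrix glycoproteins had 21 of 25 members higher and 1 lower, or 23 and 1 adjusted over the list alone, with THBS2 at 2.41 ± 0.16 and FN1 at 1.57 ± 0.15. For collagens, the median log2 change was 0.63, with camera adjusted p = 1.01e-08, and adjusted p = 0.202 with an estimated correlation (7.93e-10 to 0.248 over the alternatives of camera). Matrix proteases had 11 of 18 higher and 1 lower, or 12 and 1 adjusted over the list alone, with MMP9 higher by at least 2.41 counted from 6.64 and MMP2 at 1.38 ± 0.19. For matrix proteases, the median log2 change was 0.64, with camera adjusted p = 3.50e-04, and adjusted p = 0.0945 with an estimated correlation (9.53e-05 to 0.132 over the alternatives of camera). Cell cycle genes had 34 of 48 lower and 0 higher, or 35 and 0 adjusted over the list alone. For cell cycle genes, the median log2 change was -0.66, with camera adjusted p = 6.00e-13, and adjusted p = 0.132 with an estimated correlation (1.11e-14 to 0.132 over the alternatives of camera). Amino acid and unfolded protein response genes had 20 of 36 higher and 4 lower, or 24 and 4 adjusted over the list alone, with DDIT4 at 2.32 ± 0.13 and ASNS at 1.07 ± 0.12. For amino acid response genes, the median log2 change was 0.51, with camera adjusted p = 2.84e-05, and adjusted p = 0.202 with an estimated correlation (9.76e-06 to 0.202 over the alternatives of camera). Cholesterol synthesis had 10 of 16 higher and 0 lower, the same as adjusted over the list alone, with DHCR7 at 1.20 ± 0.18. For cholesterol synthesis, the median log2 change was 0.45, with camera adjusted p = 3.04e-04, and adjusted p = 0.226 with an estimated correlation (2.43e-05 to 0.266 over the alternatives of camera). Fatty acid synthesis had 8 of 14 higher and 1 lower, the same as adjusted over the list alone, with SCD at 1.41 ± 0.13 and FASN at 1.97 ± 0.41. For fatty acid synthesis, the median log2 change was 0.40, with camera adjusted p = 0.00710, and adjusted p = 0.202 with an estimated correlation (0.00405 to 0.266 over the alternatives of camera). The call for fatty acid synthesis was also lost without probe sets that can bind several transcripts (adjusted p = 0.124). There its median log2 change was 0.24.

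Inflammatory cytokines had 8 of 13 members higher, the same as adjusted over the list alone. For inflammatory genes, the median log2 change was 0.44, with camera adjusted p = 6.27e-04, and adjusted p = 0.0945 with an estimated correlation (2.88e-04 to 0.132 over the alternatives of camera). In the interferon response 10 of 16 were higher and 2 lower, or 12 and 2 adjusted over the list alone, with IFITM1 higher by at least 1.21 counted from 6.64 and ISG15 at -0.83 ± 0.16. For interferon genes, the median log2 change was 0.54, with camera adjusted p = 0.00301, and adjusted p = 0.217 with an estimated correlation (0.00148 to 0.266 over the alternatives of camera). The call for interferon genes was also lost with the filter at the 60th percentile (adjusted p = 0.0679). Hypoxia and glycolysis genes had 17 of 33 higher and 2 lower, or 19 and 3 adjusted over the list alone. For hypoxia genes, the median log2 change was 0.41, with camera adjusted p = 6.27e-04, and adjusted p = 0.202 with an estimated correlation (2.88e-04 to 0.202 over the alternatives of camera). Angiogenesis and growth factor genes had 8 of 14 higher and 1 lower, the same as adjusted over the list alone. For angiogenesis genes, the median log2 change was 0.43, with camera adjusted p = 0.00710, and adjusted p = 0.132 with an estimated correlation (4.98e-04 to 0.142 over the alternatives of camera). Lysosome and autophagy genes had 10 of 23 higher and 1 lower, or 12 and 2 adjusted over the list alone. For lysosome genes, the median log2 change was 0.27, with camera adjusted p = 0.00710, and adjusted p = 0.391 with an estimated correlation (0.00194 to 0.438 over the alternatives of camera). Integrins had 6 of 21 higher and 1 lower, the same as adjusted over the list alone. For integrins, the median log2 change was 0.26, with camera adjusted p = 0.0394, and adjusted p = 0.226 with an estimated correlation (0.00105 to 0.402 over the alternatives of camera). The call for integrins was also lost without probe sets that can bind several transcripts (adjusted p = 0.402), with the ACTB covariate (0.0535), without MTAP-negative replicate 3 (0.0618) or without inhibitor-treated replicate 1 (0.0510).

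MAPK immediate early and feedback genes had 10 of 20 members higher and 3 lower, or 11 and 3 adjusted over the list alone, with SPRY2 at 1.35 ± 0.12. For MAPK genes, the median log2 change was 0.47, with camera adjusted p = 0.0130, and adjusted p = 0.236 with an estimated correlation (0.00735 to 0.236 over the alternatives of camera). Heat shock proteins had 6 of 14 lower, or 8 adjusted over the list alone. For heat shock proteins, the median log2 change was -0.28, with camera adjusted p = 0.00145, and adjusted p = 0.202 with an estimated correlation (6.75e-04 to 0.266 over the alternatives of camera). Ribosome biogenesis had 8 of 22 lower, the same as adjusted over the list alone. For ribosome biogenesis, the median log2 change was -0.19, with camera adjusted p = 0.00810, and adjusted p = 0.226 with an estimated correlation (0.00148 to 0.226 over the alternatives of camera). Methionine salvage had 3 of 5 lower, the same as adjusted over the list alone: ADI1 (-0.68 ± 0.11), ENOPH1 (-0.50 ± 0.09) and APIP (-0.36 ± 0.12). APIP did not pass without MTAP-negative replicate 1 (adjusted p = 0.0724) or 2 (0.109), or without inhibitor-treated replicate 1 (0.116), 2 (0.0583) or 3 (0.0836), with adjusted p from 0.0118 to 0.116 over its alternatives. For methionine salvage, the median log2 change was -0.36, with camera adjusted p = 0.0372, and adjusted p = 0.226 with an estimated correlation (0.0224 to 0.315 over the alternatives of camera). The call for methionine salvage was also lost with the mean of its probe sets (adjusted p = 0.0566), without MTAP-negative replicate 3 (0.0608) or without inhibitor-treated replicate 3 (0.0512). Ribosomal proteins had 2 of 29 members higher, RPL3 (0.25 ± 0.09) and RPS9 (0.41 ± 0.12), or 0 adjusted over the list alone. RPL3 did not pass in 11 alternatives, among them without MTAP-negative replicate 1 (adjusted p = 0.1), 2 (0.0811) or 3 (0.0756), without MTAP-positive replicate 3 (0.0533), or without inhibitor-treated replicate 1 (0.127), 2 (0.0754) or 3 (0.115), with adjusted p from 0.00366 to 0.130 over its alternatives. RPS9 did not pass with the mean of its probe sets (adjusted p = 0.0530), with the ACTB covariate (0.0828), without MTAP-negative replicate 2 (0.0593) or 3 (0.0665), or without inhibitor-treated replicate 1 (0.0592) or 3 (0.0575), with adjusted p from 0.00568 to 0.0828 over its alternatives. For ribosomal proteins, the median log2 change was 0.16, with camera adjusted p = 0.0394, and adjusted p = 0.427 with an estimated correlation (0.0301 to 0.441 over the alternatives of camera). The call for ribosomal proteins was also lost without the filter (adjusted p = 0.0560), with arrays centred on medians (0.112), with a renewed quantile normalisation (0.0735), without MTAP-negative replicate 3 (0.0510), or without inhibitor-treated replicate 1 (0.0565) or 3 (0.0781). Polyamine genes had 4 of 16 higher and 5 lower, or 5 and 5 adjusted over the list alone, with ODC1 at -0.77 ± 0.12 and ARG2 at 1.25 ± 0.14. For polyamine metabolism, the median log2 change was -0.06, with camera adjusted p = 0.655, and adjusted p = 0.662 with an estimated correlation (0.0368 to 0.945 over the alternatives of camera).

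The design also allows the genes that differed with MTAP to be followed under the inhibitor. Most kept their difference from MTAP-negative cells: PTGES, SCG2, NR4A2 and PAEP were among those higher in both comparisons, and MMP3, DKK1, F3 (-1.30 ± 0.13, log2 ± SE, n = 3) and EPB41L4B (-1.48 ± 0.18) among those lower in both. Of the 1336 genes, 975 (73.0%) also differed in the same direction between inhibitor-treated and MTAP-negative cells, 621 higher and 354 lower. Another 8 differed in the opposite direction and 353 did not pass. The inhibitor itself moved 145 of the 1336 genes back, 82 of the higher and 63 of the lower ones, and moved 111 further, 61 up and 50 down. The other 1080 did not pass for the inhibitor.

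Genes that rose with MTAP and rose further with inhibitor included PAEP, PAX8-AS1 (at least 0.91 with MTAP, counted from 6.64, and 1.83 ± 0.24 with inhibitor), TXNIP (2.11 ± 0.21 and 1.64 ± 0.21) and the ubiquitin ligase FBXO32 (1.15 ± 0.24 and 1.15 ± 0.24). FBXO32 did not pass without inhibitor-treated replicate 3 (adjusted p = 0.0590), with adjusted p from 0.00441 to 0.0590 over its alternatives. Those that fell and fell further included CCNE2 (-0.70 ± 0.21 with MTAP), TMEM201 (-0.67 ± 0.14 and -0.94 ± 0.14) and the centrosomal genes CEP78 (-0.64 ± 0.14 and -0.94 ± 0.14) and STIL (-0.67 ± 0.15 and -0.62 ± 0.15). For TMEM201, 1 of 2 probe sets had the opposite sign under the inhibitor. With MTAP, CCNE2 did not pass in 8 alternatives, among them without MTAP-negative replicate 1 (adjusted p = 0.0801), 2 (0.139) or 3 (0.0555), without MTAP-positive replicate 1 (0.118) or 3 (0.133), or without inhibitor-treated replicate 1 (0.0574) or 3 (0.0565), with adjusted p from 0.00158 to 0.139 over its alternatives. For the inhibitor, STIL did not pass without MTAP-positive replicate 1 (adjusted p = 0.0561) or 2 (0.0529), or without inhibitor-treated replicate 1 (0.0583) or 3 (0.0555), with adjusted p from 0.00908 to 0.0583 over its alternatives. With MTAP, STIL did not pass without MTAP-positive replicate 3 (adjusted p = 0.0501), with adjusted p from 0.00229 to 0.0501 over its alternatives. Genes that rose with MTAP and moved back with inhibitor were led by TOR4A (0.80 ± 0.16 and -0.84 ± 0.16), TLCD1 (0.80 ± 0.10 and -0.77 ± 0.10), the netrin NTN4 (0.77 ± 0.15 and -0.79 ± 0.15) and the peroxisomal oxidase ACOX2 (0.73 ± 0.16 and -0.90 ± 0.16). With MTAP, TOR4A did not pass with the ACTB covariate (adjusted p = 0.0897), with adjusted p from 9.37e-04 to 0.0897 over its alternatives. ACOX2 did not pass with the ACTB covariate (adjusted p = 0.104), with adjusted p from 0.00672 to 0.104 over its alternatives. Genes that fell with MTAP and returned were led by SUSD1 (-1.31 ± 0.17 and 1.60 ± 0.17), the ubiquitin ligase HECW2 (-0.99 ± 0.13 and 1.13 ± 0.13), ATP8B1 (-1.24 ± 0.18 and 0.99 ± 0.18) and ADAMTS6 (-1.74 ± 0.16 and 0.97 ± 0.16). For ATP8B1, 1 of 2 probe sets had the opposite sign with MTAP.

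**Figure D4:**
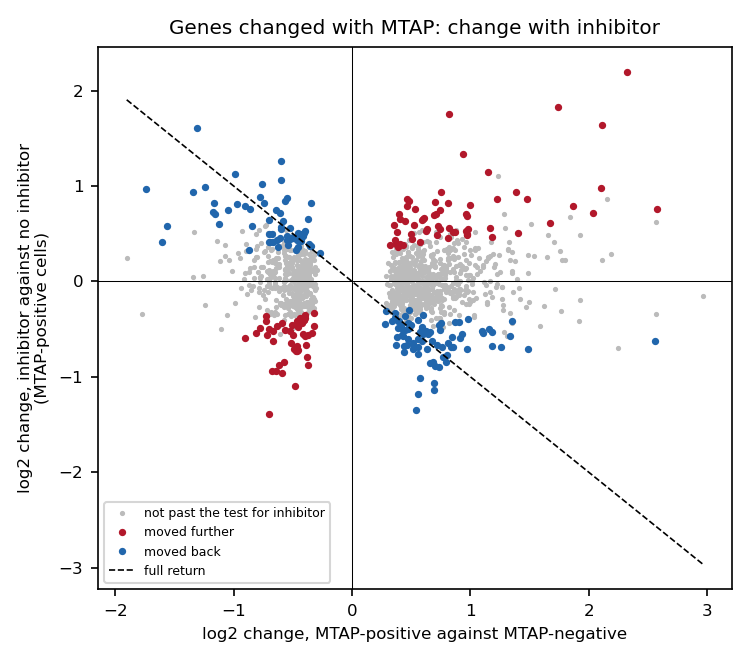
Each of the 1336 genes that differed with MTAP, by its log2 change with MTAP (x axis) and its log2 change with inhibitor in MTAP-positive cells (y axis); red points moved further, blue points moved back, grey points did not pass for the inhibitor, and the dashed line marks a full return. Of the 1336 points 111 are red and 145 blue.

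Independent lists of these sizes would share 251 genes in the same direction between the comparisons against MTAP-negative cells, against 975 observed. They would give 103 genes moved back and 96 moved further, against 145 and 111 observed. Over the 7010 genes, the change with MTAP and the change of inhibitor-treated against MTAP-negative cells correlated at 0.759, where 100 simulations of independent arrays without effect gave a mean of 0.5. In simulations added after the data were seen, same-numbered arrays correlated at the observed means: 0.260 with and without MTAP, 0.572 with and without inhibitor, and 0.122 between inhibitor-treated and MTAP-negative cells. The mean then was 0.740 (0.720 to 0.756), close to the observed value. The covariance was 0.145, against means of 0.0114 and 0.0137 in these simulations. The change with MTAP and the change with inhibitor correlated at -0.0028, against -0.499 for independent and -0.256 for paired arrays. Their covariance was -3.49e-04 against -0.0114 and -0.0033. Genes are not independent replicates, and shared arrays may give part of the overlap, as 3 cannot be split into groups of at least 2. The 975 genes became 411 with the ACTB covariate, 1604 with array weights, 576 without MTAP-positive replicate 3 and 583 without MTAP-negative replicate 3. Without inhibitor-treated replicates 3, 2 and 1, the 145 moved back became 46, 79 and 75, and the 111 moved further 39, 54 and 57. Those moved back became 76 without MTAP-positive replicate 1 and 92 without MTAP-negative replicate 3. Those moved further became 62 and 71 without MTAP-positive replicates 1 and 3, and 71 and 67 without MTAP-negative replicates 1 and 3. The replicate block gave 285 moved back and 234 further, array weights 338 and 313, and the ACTB covariate 45 and 49.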

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

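The tests of a deviating array and of shared arrays and the fit with the ACTB covariate below were chosen only after the results were seen. The tests of RNA quality and of other splits of the arrays were fixed earlier.

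Probe sets that carried several gene symbols or none were outside every comparison of genes, and many of them changed too. Of 1173 such probe sets above the filter level, 610 with several symbols, 158 differed between MTAP-positive and MTAP-negative cells, 94 higher and 64 lower. With inhibitor 162 changed in MTAP-positive cells, 86 higher and 76 lower, and 395 differed between inhibitor-treated and MTAP-negative cells, 217 higher and 178 lower. They stand out only as signal in data that the gene comparisons leave out.

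The first pattern is the number of genes that changed with MTAP (1336) and with the inhibitor (1042), to which RNA degradation could contribute, since MTAP-negative cells had the most negative mean ACTB control difference, below MTAP-positive cells in all 3 same-numbered pairs. The slope of the called genes on that difference within groups predicted a part of 0.0282 of their change with MTAP (-0.0167 to 0.0709 with 1 array left out). For their change with the inhibitor the part was 0.0174 (-0.0013 to 0.0530). A call needs little spread within groups, which selects against genes that follow the control difference there. These parts are thus low partly by selection and cannot decide how far degradation contributed. With that difference as a covariate 470 genes changed with MTAP, as the median SE of the called genes went from 0.122 to 0.156 and their median absolute log2 change from 0.56 to 0.54. Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many genes in each comparison, 2613 in inhibitor-treated against MTAP-negative cells included, and the highest other split gave 0, but 10 splits are too few for a share under 0.05. RNA degradation, how the MTAP-positive cells were derived, culture differences and the enzyme itself stay open for the MTAP comparison, as nothing in the design separates them.

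The second pattern is the fall of cell cycle and replication genes with the inhibitor, such as CCNE2 and NCAPG. RNA quality predicted a part of 0.0317 of the list's mean change (-0.0024 to 0.0636 with 1 array left out). The mean log2 change was -0.54 and lay nearest to 0 at -0.49 without inhibitor-treated replicate 3, so a single deviating array does not account for it. Slower growth of the treated cells, by inhibition of MTAP or by another action of the compound, may be a cause and stays an untested hypothesis, as MTAP-negative cells with inhibitor were not measured. The call itself ended with an estimated correlation (adjusted p = 0.226, over alternatives 1.52e-15 to 0.226).

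The third pattern is that most genes changed with MTAP, such as PTGES and MMP3, stayed changed under the inhibitor, where both comparisons use the MTAP-negative arrays, which alone gives agreement. The covariance over genes was 0.145, while 100 simulations without effect ranged from 0.0103 to 0.0127, or from 0.0128 to 0.0151 with same-numbered arrays correlated, so shared arrays in these simulations do not account for all of it. The correlation of 0.759 lay close to the 0.720 to 0.756 of the simulations with correlated arrays. Unlike the covariance, a correlation leaves out the size of the changes, and these simulations held no real changes. By itself it neither tells the pattern from shared arrays nor shows that they account for it. Effects of MTAP that do not need its activity, incomplete or too short inhibition, and differences between the cell stocks unrelated to MTAP may each give this pattern, and the design cannot separate them. MTAP activity and methylthioadenosine were not measured here.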

How the results depend on the processing

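The fit with the ACTB difference as a covariate and the replicate block combined with an estimated correlation were chosen only after the data were seen. Of 216 results for named genes, 203 were called, and 155 of these kept the call in every alternative that tested the gene. Some alternatives did not test all of them. Without probe sets that can bind several transcripts 133 of the 216 results had a value, all on the same side of the threshold. Over the alternatives scored for genes 4013 gene values stayed on their side of the threshold, 158 lost the call, 11 gained it and 0 called values changed direction. Of 81 list results, 36 were called, and 0 passed under every alternative, since 0 lists passed in any comparison when camera used an estimated correlation, with or without the replicate block, against 12, 7 and 17 with the preset one. The lowest adjusted p with an estimated correlation was 0.113, 0.226 and 0.0945. In all, 117 list values lost the call, 30 gained it and 1710 stayed, or 115, 20 and 1641 without fry, which answers another question. Fry, which asks whether a list moves one way without comparing it with other genes, called 14, 7 and 23 of 27 lists, and its test for change in either direction 27, 26 and 27. The excess of rises among genes changed with MTAP (61.4%) became 43.2% with arrays centred on their medians and 48.0% with a renewed quantile normalisation, and the median of all genes moved by under 0.1 on the log2 scale. In inhibitor-treated against MTAP-negative cells the 1351 higher and 1262 lower genes became 1142 and 1565 when arrays were centred.

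Counts moved by over 1.5 times in these settings. With array weights, 2164 genes changed with MTAP and 1832 with the inhibitor, 1604 genes kept the same call against MTAP-negative cells under inhibitor, 338 moved back and 313 further. With only the 2 groups fitted, 752 genes changed with MTAP, from fewer arrays behind the spread. With the replicate block, 1589 genes changed with the inhibitor, 285 genes moved back and 234 further. The block also gave 3216 genes for inhibitor-treated against MTAP-negative cells, whose arrays share no more than a number. With the ACTB covariate, 470 genes changed with MTAP, 411 kept the same call, 45 moved back and 49 further. There the SE grew more than the changes shrank. A threshold of 0.01 gave 502, 354 and 1517 genes in the 3 comparisons, by construction. In inhibitor-treated against MTAP-negative cells 1732 genes changed without the probe sets that can bind several transcripts, where fewer genes were tested, and 3961 probe sets when all were tested. For array weights and the replicate block the cause was not tested.

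With 1 array left out, genes changed with MTAP ranged from 745 (without MTAP-negative replicate 3) to 1583 (without MTAP-positive replicate 2), and those changed with the inhibitor from 372 (without inhibitor-treated replicate 3) to 1055 (without MTAP-negative replicate 2). Inhibitor-treated against MTAP-negative cells gave 1844 (without inhibitor-treated replicate 3) to 2959 (without MTAP-positive replicate 2). Genes with the same call ranged from 576 to 1182, those moved back from 46 to 141 and those moved further from 39 to 96, while the share with the same call was 66.8% to 80.9%. Lists called ranged from 10 to 12, 6 to 9 and 15 to 17. Fewer arrays widen the errors, and whether single arrays deviate for another reason was not tested. The deposited table held only probe sets with values at or above 6.64 on at least 3 arrays, so genes near background could not be examined.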

Other observations

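The test of FOXO target genes below was chosen only after the results were seen, and the other lists were fixed earlier. TGF-beta and YAP targets moved in both directions with MTAP. The feedback inhibitor PMEPA1 rose by 1.70 ± 0.15 and the receptor TGFBR2 by 1.39 ± 0.08 (log2 ± SE; limma, n = 3), and 7 of 22 members were higher and 5 lower, against 4 and 3 with the inhibitor and 7 and 1 between inhibitor-treated and MTAP-negative cells. Adjusted over the list alone, 7 and 6, 5 and 3, and 7 and 1 were higher and lower. Camera adjusted p = 0.608, 0.0571 and 0.190 in these comparisons, and in the last one the median of -0.01 and the mean of 0.34 differed in sign. Wnt pathway genes had 3 of 13 higher and 3 lower with MTAP, 2 and 2 with inhibitor and 5 and 3 in the last comparison (camera adjusted p = 0.667, 0.435 and 0.493), or 5 and 3, 2 and 2, and 5 and 4 adjusted over the list alone. With MTAP the receptor FZD7 rose by 1.16 ± 0.11 while DKK1 and DKK3 fell, and the list's median of 0.18 and mean of -0.01 differed in sign. MAPK feedback genes were not called with MTAP (7 higher and 1 lower of 20, or 8 and 3 adjusted over the list alone, camera adjusted p = 0.0924) or with the inhibitor (4 and 1, the same over the list alone, adjusted p = 0.0897), with SPRY2 at 1.13 ± 0.12 with MTAP and the phosphatase DUSP5 at 1.07 ± 0.12 with inhibitor.

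Targets of p53 had 1 of 23 higher and 3 lower with MTAP, 2 and 2 with inhibitor and 3 and 10 between inhibitor-treated and MTAP-negative cells (camera adjusted p = 0.148, 0.671 and 0.141), the last with TP53I3 at -0.89 ± 0.13 and GDF15 at 0.88 ± 0.13. NRF2 targets had 1 of 16 higher and 3 lower, 1 and 1, and 2 and 3 (camera adjusted p = 0.409, 0.889 and 0.350), or 1 and 3, 1 and 2, and 2 and 3 adjusted over the list alone, with the glutamate-cysteine ligase subunit GCLM at -1.16 ± 0.17 in the last comparison. Oxidative phosphorylation genes had 1 of 38 higher and 2 lower, 0 and 3, and 2 and 7 (camera adjusted p = 0.608, 0.975 and 0.655), or 0 and 0, 0 and 2, and 1 and 6 adjusted over the list alone. Cancer-testis antigens had 1 of 8 higher and 0 lower, 0 and 0, and 0 and 3 (camera adjusted p = 0.728, 0.153 and 0.220). With an estimated correlation none of these lists passed, and the lowest adjusted p of any list was 0.113, 0.226 and 0.0945. The median also differed in sign from the mean or the test for ribosome biogenesis and polyamine genes with inhibitor, and for methionine and folate cycle and oxidative phosphorylation genes in the last comparison, with medians close to 0. Markers of other cell types were mostly without values: 5 of 24 epithelial, 2 of 20 blood, 3 of 13 endothelial or smooth muscle, 4 of 16 neural or melanocyte and 0 of 13 liver markers had values, and 2, 0, 2, 3 and 0 were tested. Among them the endothelial receptor TIE1 rose by a log2 change of 0.61 ± 0.15 with MTAP and MITF, a regulator of pigment cells, fell by -0.82 ± 0.14. With inhibitor the neurofilament NEFL fell by -0.82 ± 0.15 and the tubulin TUBB3 by -0.49 ± 0.13. Between inhibitor-treated and MTAP-negative cells TIE1 differed by 0.94 ± 0.15, MITF by -1.19 ± 0.14 and TUBB3 by -0.52 ± 0.13. TIE1 did not pass with only the 2 groups fitted (adjusted p = 0.0598), with the ACTB covariate (0.0590) or without MTAP-positive replicate 3 (0.0762), with adjusted p from 0.00526 to 0.0762 over its alternatives. TUBB3 did not pass without MTAP-positive replicate 1 (adjusted p = 0.0808) or 2 (0.0659), or without inhibitor-treated replicate 1 (0.0781), 2 (0.0503) or 3 (0.120), with adjusted p from 0.00543 to 0.120 over its alternatives.

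TXNIP and FBXO32, both known as targets of the FOXO transcription factors, rose with MTAP and further with the inhibitor, which led to the hypothesis that FOXO activity may be raised. A list of other FOXO targets was written after these values had been seen and after many others had been read, so its test is exploratory. Its 13 tested members without TXNIP and FBXO32 had a median log2 change of 0.30 with inhibitor, 2 higher and 1 lower, of 0.0819 with MTAP, 4 higher and 1 lower, and of 0.39 between inhibitor-treated and MTAP-negative cells, 5 higher and 1 lower. Camera, adjusted over these 3 comparisons, gave adjusted p = 0.175, 0.218 and 0.0774, and with an estimated correlation adjusted p = 0.513 in each. The member lower with MTAP and in the last comparison was G6PC3, a doubtful FOXO target. Without it, a choice made after its values were seen, adjusted p = 0.0726, 0.0894 and 0.0158, and with an estimated correlation adjusted p = 0.372 in each. A first version of the list had 15 members, of which GADD45A and MXI1 were taken out after it had been run, because their values had been seen. That version gave adjusted p = 0.0442, 0.174 and 0.0255, and with an estimated correlation adjusted p = 0.314, 0.413 and 0.314. The camera results for the inhibitor and for inhibitor-treated against MTAP-negative cells thus crossed 0.05 through the choice of members, and the data neither show nor exclude the hypothesis.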
